A study of Arabidopsis thaliana with 6 samples.

How the data were processed

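Gene expression was measured in vegetative apices of Arabidopsis thaliana, Columbia background, grown for 7 days in short days. The 6 arrays fall into 3 groups of 2: plants carrying the empty plasmid pML-BART (vector), plants overexpressing the microRNA miR164b and plants overexpressing miR172a. Groups were taken from the sample descriptions, and the replicate number from the letter that ends each sample title. Nothing in the labels states whether the 2 arrays of a group came from separate plants or pools, so p-values measure the spread between these samples, which may be technical.

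The authors deposited 1 linear intensity for each of 22810 probe sets and array, with 1 decimal and no negative values. Per the labels no software is named, and the summary method and scaling program are not given in the sources used here. The mean of the deposited intensities of every array, taken without the lowest and highest 2% of its probe sets, was 200. Median intensities lay between 85.3 and 92.2. Detection calls were not used here, so no probe set is described as absent, and the number of arrays limits the precision of every value.

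The 64 AFFX control probe sets were kept out of the tests, which left 22746. Gene names came from the array annotation supplied with the data and were updated through the TAIR10.1 gene table, used for names only. Of the tested probe sets, 13513 paired with 1 gene, 503 with several genes and 8730 were not listed in that annotation, so they are unnamed here and may well represent genes. Of the probe sets with 1 gene, 13436 matched the gene table. The named probe sets stood for 13356 genes. For the 146 genes with more than 1 probe set, the brightest stood for the gene. SQN was such a gene, and its probe sets differed in sign between miR172a and vector (log2 -0.01 and 0.21) and between the lines (log2 0.28 and -0.21), none past the threshold.

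Values were transformed as log2(intensity + 16), because the deposited scale is linear, and no further normalization was applied. The offset shrinks changes of dim probe sets: 3482 probe sets lay below 16 on all 6 arrays. A linear model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 (lmFit and eBayes, without trend or robust option) in R 4.3.3. It had 3 residual and 2.69 prior degrees of freedom. The 3 contrasts were miR164b against vector, miR172a against vector and miR164b against miR172a. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets of a contrast, with a threshold of 0.05. All tests were two-sided. At every call the arrays of one group lay on one side of those of the other, which chance alone gives for 33.3% of arrangements. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

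Gene lists were tested with camera of limma, with 1 probe set per gene, a preset correlation of 0.01 between genes and, as an alternative, a correlation estimated from the arrays. The latter test also has only the 3 residual degrees of freedom. After it had called 0 of the added lists, each was also tested with its own estimate, or 0 where that was negative, in place of the preset correlation and nothing else changed. Lists needed 3 measured genes. Adjustment ran over the tested lists of a contrast. The contrasts, the threshold, the alternatives named below and 25 lists with 287 genes were fixed before the data were examined. Only 32 of these genes had a named probe set, 11 lists had none and 5 could be tested. A further 16 lists were therefore written from the named genes after the annotation, the array distributions and the control probe sets had been seen and before any fold change was computed. Another 20 families of at least 10 genes sharing a symbol stem, and the plastid and mitochondrial genomes, were added after a fit had shown the largest changes. These 38 added lists have 645 members and were adjusted together. The results of 2 of the families are not reported here.

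Genes named in the text follow 1 rule, fixed with the lists: every measured member of the miR164 and miR172 target lists, the 10 largest rises and the 10 largest falls of a contrast among genes past the threshold whose arrays do not overlap, and up to 4 members of a list with the smallest p. Where no member passed, up to 2 with the largest change may be given as values, and these are left out here apart from the target list. The same rule for members past the threshold was applied to the added lists. Other genes named were chosen after their values were seen, and the text says so.

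The method was tested on simulated arrays built on each probe set's mean over the 6 arrays, with spreads drawn from the prior that limma fitted. Each of 10 draws changed 200 of 22746 probe sets per contrast. For miR164b against vector, 67.4% of probe sets changed by 1 on the log2 scale and 95.6% of those changed by 2 were recovered. For miR172a against vector the shares were 62.0% and 94.0%. Of changes of 0.5, 1.8% and 2.4% were recovered. False calls made up 4.31% and 5.11% of the calls. At an unadjusted p under 0.05, camera called a random list of 20 probe sets shifted by 0.5 in 20 of 20 draws for miR164b against vector. It called an unshifted list in 1. The simulated probe sets varied independently and followed the model that the tests assume. These shares therefore check the code and its power under that model, not the tests on correlated genes.

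Alternatives were quantile normalization, median centring, removal of the 40% dimmest probe sets, offsets of 1 and 64, a trended and robust prior, a fit to the 4 arrays of a contrast, the replicate number as a block, omission of each array in turn, another rule for calls, a threshold of 0.10 and other list tests. A vector array of its own for each line, in the count of shared calls, was added after that count had been seen. Samples with the same replicate number were not treated as pairs. With 2 arrays against 2, a permutation of the arrays cannot give a small p-value, so no permutation test was used.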

Results

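Transcript levels were compared on 6 Affymetrix arrays of vegetative apices from 7-day-old plants, 2 arrays each for empty vector, miR164b overexpression and miR172a overexpression. The question behind the design is which transcripts differ when either microRNA is overproduced before flowering. Levels below are scaled intensities as mean ± SD (n = 2), and log2 changes are on the log2(intensity + 16) scale with their standard errors. Arrays of a group correlated at 0.991 (vector), 0.994 (miR164b) and 0.9915 (miR172a) across probe sets, and arrays of different groups at 0.981 to 0.9872. The first principal component held 40.5% of the variance and set miR172a apart, and the second, with 28.4%, set vector apart. The 25S rRNA control read 4070 and 4093 on the vector arrays, 443 and 529 on the miR164b arrays, and 355 and 3462 on miR172a arrays 1 and 2. The ratio of the 3' to the 5' actin control was 3.0 and 2.94 in vector, 1.96 and 2.11 in miR164b, and 2.25 and 3.05 in miR172a.

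No gene of the miR164 target list had a named probe set, and the microRNAs themselves were not measured, so the overproduction of miR164b was not checked here. Of the 6 miR172 targets, SMZ (AT3G54990) and SNZ (AT2G39250), which encode AP2-type floral repressors, were measured. SNZ was higher on the arrays labelled miR172a, at 223 ± 18.8 against 117 ± 13.1 in vector (log2 0.85 ± 0.11, adjusted p = 0.017). This is opposite to a lowered target mRNA, so these values do not check the label, and every direction below rests on the labels alone. SMZ read 174 ± 4.8 on the arrays labelled miR172a and 160 ± 3.5 in vector (log2 0.11 ± 0.08, adjusted p = 0.506). On the miR164b arrays SNZ read 95.2 ± 3.5 and SMZ 168 ± 1.2, and neither passed the test against vector (adjusted p = 0.298 and 0.716). Adjusted over the list alone, SNZ remained the 1 gene called in miR172a. The SNZ call was lost with an offset of 1 and when any one of the 6 arrays was left out, with adjusted p between 0.0016 and 0.0944 over all alternatives.

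The comparison of miR164b with vector asks which transcripts differ when miR164b is overproduced. BCAT4 (AT3G19710), an aminotransferase of methionine-derived glucosinolate synthesis, rose from 36.9 ± 3.9 to 764 ± 22.7 (log2 3.89 ± 0.09, adjusted p = 2.8e-04). GSTU20 (AT1G78370), a glutathione transferase, rose from 592 ± 15.3 to 2902 ± 261 (log2 2.26 ± 0.09, adjusted p = 0.0016). The glucosyltransferase gene AT2G31790 rose from 206 ± 19.9 to 837 ± 34.4, and the oxygenase gene AT2G25450 from 717 ± 22 to 2094 ± 134. UGT74B1 (AT1G24100), a glucosyltransferase of glucosinolate synthesis, rose from 250 ± 12.7 to 589 ± 40.6 (log2 1.18 ± 0.09, adjusted p = 0.0079). XTH19 (AT4G30290), a xyloglucan endotransglucosylase, rose from 20.9 ± 5.1 to 112 ± 5.1 (log2 1.80 ± 0.13, adjusted p = 0.0057). AT5G12940, AT5G62360, AT5G51890, AT2G43550 and AT1G05310 completed the 10 largest rises, with log2 changes between 1.65 and 1.28.

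Among the 10 largest falls in miR164b, LEA4-5 (AT5G06760), a late embryogenesis abundant protein, fell from 148 ± 15.4 to 7.40 ± 4.4 (log2 -2.81 ± 0.27, adjusted p = 0.013). That log2 change was -4.25 with an offset of 1, where the call was lost, and -1.57 with 64 (adjusted p from 0.0013 to 0.142 over the alternatives). AT3G02480, of the same class, fell from 335 ± 40.2 to 31.9 ± 1.6 (log2 -2.87 ± 0.18, adjusted p = 0.0037), and AT3G17520 from 62.6 ± 6.7 to 7.60 ± 2.7. HIS1-3, a drought-inducible linker histone, fell from 359 ± 6.6 to 108 ± 6.9. Of the added cold and dehydration list, LEA4-5 and the dehydrin gene LTI30 fell, and the list itself did not pass (adjusted p = 0.0603). LTI30 fell from 466 ± 13.5 to 190 ± 1.8 (log2 -1.22 ± 0.09, adjusted p = 0.0062). The rest of the 10 were AT1G19530, AT2G37870, AT4G39675, AT5G61820, AT3G53980 and AT5G53710, with log2 changes between -2.76 and -1.46.

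Of the 32 measured members of the fixed lists, 2 passed in miR164b, and 5 did adjusted over the list alone. ARR15, a response regulator induced by cytokinin, rose from 99.7 ± 4.4 to 203 ± 4.0 (adjusted p = 0.031). WES1, an auxin-conjugating enzyme, fell from 982 ± 1.9 to 686 ± 5.5 (adjusted p = 0.0499). The WES1 call was lost in 10 of 14 alternatives, median centring and each single array among them (adjusted p from 0.0041 to 0.269), and that of ARR15 in 6. By camera 0 of the 5 tested fixed lists shifted, and 0 had an unadjusted p under 0.05, and 3 of them, for floral genes, boundary genes and root markers, had median, mean and test of different sign. Among the added lists, 4 of 38 shifted. Of 28 expansins and xyloglucan hydrolases, 4 rose and 0 fell: XTH19, EXPA8 (195 ± 17.1 to 445 ± 17.3), XTH16 and EXPA4 (list adjusted p = 0.003; adjusted p = 0.758 with an estimated correlation). That list lost its call without vector replicate 2 (adjusted p = 0.0783). The carboxypeptidase-like family SCPL shifted upward with scpl31 and scpl48 as the 2 members of 29 that rose (adjusted p = 0.006; adjusted p = 0.758 with an estimated correlation). The PRA family shifted upward with PRA1.F1 as the 1 member of 11 that rose (adjusted p = 1.8e-04; adjusted p = 0.758 with an estimated correlation). The 69 plastid-encoded genes shifted downward by a median log2 of -0.30, with 0 genes past the threshold on their own (adjusted p = 9.2e-07; adjusted p = 0.758 with an estimated correlation). With each list's own estimate as the correlation and nothing else changed, the PRA family kept its call (adjusted p = 0.01) and the other 3 lists lost theirs. The plastid median was -0.18 without vector array 1 and -0.16 without miR164b array 1. Both miR164b arrays carried low 25S rRNA values, 443 and 529. Of 24 nuclear photosynthesis genes 0 passed, and their median log2 change was -0.03.

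In total 407 of 22746 probe sets passed in miR164b against vector, 216 higher and 191 lower, and 4199 had an unadjusted p under 0.05 where chance gives 1137. The balance was 254 higher and 155 lower with median centring, 244 and 156 with quantile normalization, and 449 and 515 at an adjusted p under 0.1. Of the 407, 60.0% carry no single gene name here, so the named genes cover 79 higher and 83 lower. The count rests on each array: it was 9 without either miR164b array, 52 without vector replicate 1 and 53 without vector replicate 2. Of 37 genes named by the rule as past the threshold, BCAT4 and GSTU20 kept their call under every alternative, and the other 35 lost it without some array. Of the 37, 8 had a group mean below 16, and all 8 lost their call with an offset of 1.

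**Figure D1:**
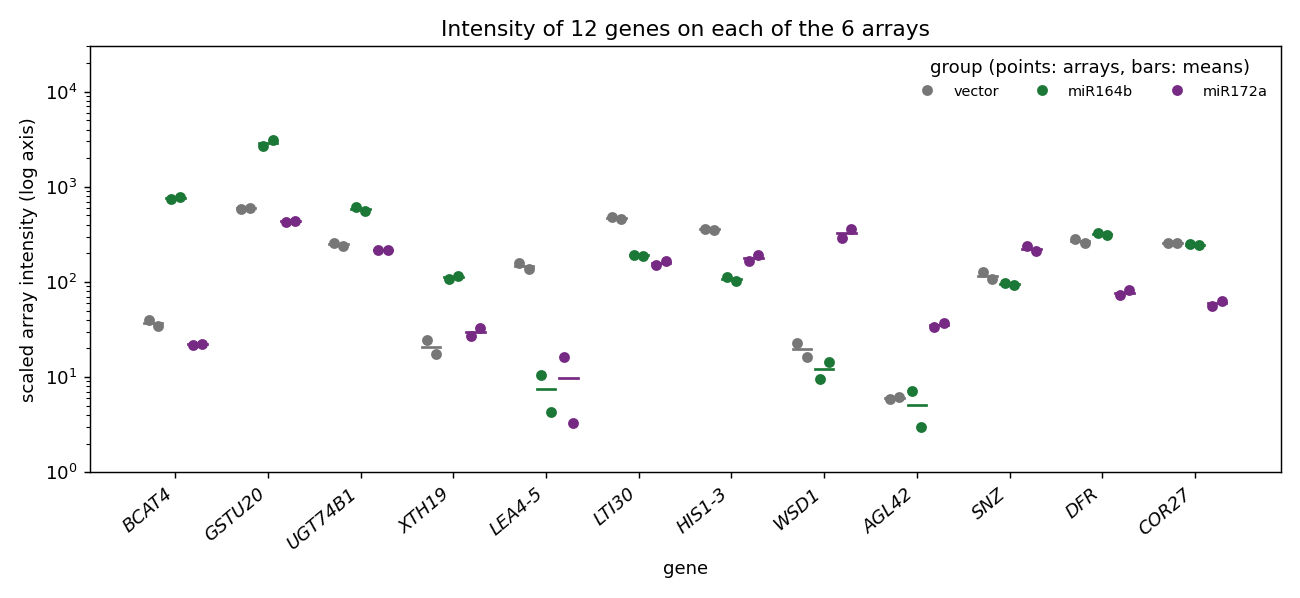
Scaled intensity on a log axis of 12 genes on each array, with points for the 2 arrays of vector, miR164b and miR172a and bars for their means. BCAT4 averaged 764 in miR164b against 36.9 in vector, LEA4-5 was lower in both lines than its 148 in vector, and WSD1 averaged 328 in miR172a against 19.5 in vector.

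The comparison of miR172a with vector asks the same of miR172a. WSD1 (AT5G37300), a wax ester synthase, rose from 19.5 ± 4.7 to 328 ± 51.2 (log2 3.27 ± 0.16, adjusted p = 0.002). AT1G67865 rose from 10.2 ± 3.3 to 307 ± 24.1 (log2 3.63 ± 0.12, adjusted p = 0.0018; log2 4.81 and 2.32 with offsets of 1 and 64, call kept) and AT1G67860 from 17.9 ± 8.4 to 133 ± 25.9. AGL42 (AT5G62165), a MADS-box gene of the floral promoter list, rose from 6.0 ± 0.14 to 35.3 ± 2.4 (log2 1.22 ± 0.12, adjusted p = 0.0087), and AGL24, a MADS-box floral promoter, from 28.8 ± 0.07 to 58.9 ± 4.8 (adjusted p = 0.039). The AGL42 change was 2.37 with an offset of 1 and 0.50 with 64. Its call was lost with an offset of 1 and without any one of the 4 vector and miR172a arrays (adjusted p from 0.0047 to 0.0703), and that of AGL24 without any one of the 6 arrays (highest adjusted p = 0.162). ATC, a relative of the floral inhibitor TFL1, rose from 3.80 ± 1.1 to 20.9 ± 0.14. Hop3, Hsp70-2 and Fes1A, of the heat shock and co-chaperone machinery, rose to 85.8 ± 3.7, 371 ± 28.8 and 314 ± 1.1 from 34.2 ± 0.7, 196 ± 10.2 and 161 ± 23.4. AT5G48570, an immunophilin gene, rose from 62.1 ± 3.4 to 239 ± 1.4 (adjusted p = 0.002). The other large rises were those of AT4G21650, AT1G19450, AT3G45680, AT5G22580, AT2G39850 and AT5G55450, with log2 changes between 2.15 and 1.73.

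COR27 (AT5G42900), a cold-regulated gene, fell from 258 ± 2.2 to 59.6 ± 5.5 (log2 -1.86 ± 0.09, adjusted p = 0.002), LTI30 from 466 ± 13.5 to 159 ± 11.6, and LEA4-5 from 148 ± 15.4 to 9.80 ± 9.2. The LEA4-5 change was -2.71, but -4.10 with an offset of 1, where the call was lost, and -1.52 with 64 (adjusted p from 0.0011 to 0.0893). DFR (AT5G42800), which reduces dihydroflavonols, fell from 271 ± 18.0 to 77.0 ± 6.1 (log2 -1.63 ± 0.10, adjusted p = 0.0026). The anthocyanin transferase genes UF3GT and AT5MAT fell from 187 ± 13.3 to 43.5 ± 5.4 and from 128 ± 16.2 to 41.6 ± 4.6. The cytokinin-induced response regulator RR16 fell from 90.7 ± 1.3 to 34.5 ± 5.3 (adjusted p = 0.008), and the clock and flowering gene GI from 496 ± 8.6 to 337 ± 8.1 (adjusted p = 0.028). JAG, which promotes growth of lateral organs, fell from 107 ± 11.6 to 59.3 ± 10.9 (adjusted p = 0.040). The GI and JAG calls were each lost in 9 of 14 alternatives, with an offset of 1, the block and each single array among them (highest adjusted p = 0.116 and 0.141), and that of RR16 in 3. The 10 largest falls also held AT3G02480, AT2G37870, AT4G34950, AT1G19530, AT2G23910, AT4G39675, AT5G62210, AT4G33980 and AT5G18600, with log2 changes between -2.99 and -1.92.

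Of the 32 measured members of the fixed lists, 8 passed in miR172a and 13 did adjusted over the list alone. They were SNZ, AGL42 and AGL24, which rose, and RR16, SAG29, DFR, GI and COR47, which fell. By camera 0 of the 5 tested fixed lists shifted, and 2 had an unadjusted p under 0.05. The floral list came nearest, with 2 of 4 members higher and an adjusted p = 0.0883 (adjusted p = 0.316 with an estimated correlation), and 3 members were higher and 1 lower adjusted over the list alone.

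Among the added lists 8 of 38 shifted in miR172a. With an estimated correlation 0 did, but that test also has only 3 degrees of freedom. With the correlation alone changed 7 of the 8 kept their call and the plastid list lost it (adjusted p = 0.57). For 5 of the 7 the estimate was below 0 and taken as 0, a laxer test than the preset one. Of 23 cell division genes 5 fell and 0 rose, among them KINESIN-12B (173 ± 7.9 to 94.9 ± 6.4), TOPII (738 ± 27.4 to 487 ± 64.8), the histone gene HTB11 and 3xHMG-box2 (list adjusted p = 2.7e-04; adjusted p = 0.384 with an estimated correlation). The TOPII, HTB11 and 3xHMG-box2 calls were each lost in 9 of 14 alternatives, each single array among them (adjusted p from 0.0054 to 0.162 over the 3 genes), and that of KINESIN-12B in 7. Of 9 cold and dehydration genes 4 fell and XERICO rose, from 297 ± 16.2 to 489 ± 10.3 (adjusted p = 0.0012; adjusted p = 0.384 with an estimated correlation). Of 8 flavonoid genes 3 fell (adjusted p = 0.0022; adjusted p = 0.384 with an estimated correlation). Of 9 heat shock and co-chaperone genes 3 rose (adjusted p = 0.0065; adjusted p = 0.384 with an estimated correlation). WSD1 was the 1 called member of 9 in the epidermis list (adjusted p = 0.038; adjusted p = 0.384 with an estimated correlation), and that list lost its call in 7 of 15 other settings. The TBL family, with TBL36, TBL43 and TBL28 higher, and the NET family, with 0 of 10 members called, shifted up and down (adjusted p = 0.0092 and 0.040; adjusted p = 0.384 for both with an estimated correlation). The TBL call was lost without the 40% dimmest probe sets, vector replicate 2 or miR172a replicate 2, and the NET call with an offset of 1 and without vector replicate 2 or either miR172a array. The 69 plastid genes shifted downward by a median log2 of -0.21, with 0 called (adjusted p = 2.1e-05; adjusted p = 0.735 with an estimated correlation), on arrays with 25S rRNA values of 355 and 3462. That median was -0.12 without vector array 1. Among nuclear photosynthesis genes PORB and HEME1, of chlorophyll and porphyrin synthesis, fell and LHCB4.3 rose, and the list did not shift (adjusted p = 0.165).

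In total 1336 probe sets passed in miR172a against vector, 735 higher and 601 lower, and 51.9% of them carry no single gene name here. The balance turned with median centring, to 639 higher and 660 lower, and without miR172a replicate 1 (77 and 85) or 2 (49 and 62). The count was 162 without miR172a replicate 1, 111 without miR172a replicate 2, 166 without vector replicate 1 and 225 without vector replicate 2. It was 359 without either miR164b array, and 21 of 73 genes named by the rule as past the threshold kept their call under every alternative. Of the 73, 8 had a group mean below 16, and 3 of these lost their call with an offset of 1.

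**Figure D2:**
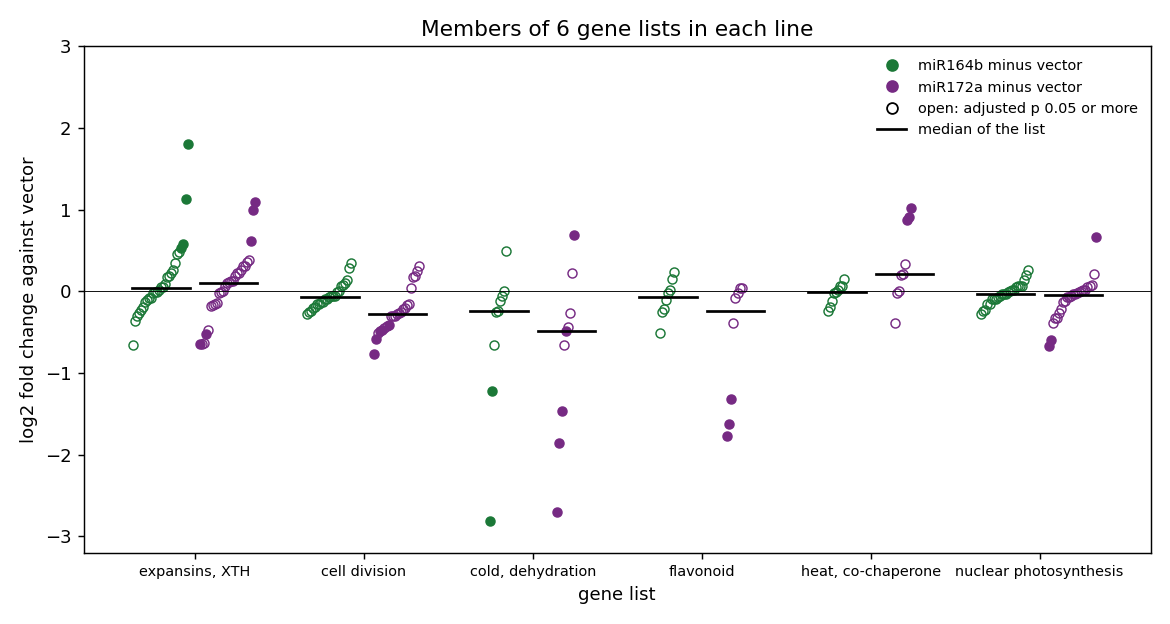
Log2 fold change against vector of each measured member of 6 added gene lists, in miR164b and in miR172a, with filled points past the threshold and a bar at the list's median. Cell division genes had 5 filled points below 0 in miR172a and 0 in miR164b, and flavonoid genes 3 and 0.

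The lines were also compared directly, which does not involve the vector arrays except through the shared estimate of spread. BCAT4 was higher in miR164b by a log2 of 4.35 ± 0.09 (764 ± 22.7 against 22.1 ± 0.49, adjusted p = 1.3e-04) and UGT74B1 by 1.38 ± 0.09. GSTU20 was higher by 2.70 ± 0.09. DFR and UF3GT were higher in miR164b by 1.86 ± 0.10 and 1.92 ± 0.10, and COR27 by 1.80 ± 0.09. ARR15 and RR16 were both higher in miR164b, at 203 ± 4.0 against 74.6 ± 13.0 and 76.2 ± 2.2 against 34.5 ± 5.3. Higher in miR172a were AGL42 at 35.3 ± 2.4 against 5.05 ± 2.9 (adjusted p = 0.0056), FD, a bZIP partner of the florigen, at 83.5 ± 10.7 against 46.5 ± 2.6 (adjusted p = 0.025), LAS, a regulator of axillary meristems, at 64.8 ± 1.3 against 41.0 ± 4.7, and SNZ at 223 ± 18.8 against 95.2 ± 3.5 (adjusted p = 0.0073). WSD1 was higher in miR172a by a log2 of 3.61 (adjusted p = 8.3e-04), and WES1 reached 1194 ± 50.3 there against 686 ± 5.5.

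The 10 largest differences toward miR164b also held AT4G34950, AT4G33980, AT2G23910, AT2G25450, AT4G28780, AT1G07050 and AT2G43550, with log2 differences between 2.98 and 1.98. Those toward miR172a held AT1G67865, AT1G67860, AT4G30450, AT5G48570, AT4G30460, AT2G37900, ATSBT5.2, UGT84A1 and AT5G22460, between -3.51 and -1.59. Of the 32 members of the fixed lists 11 passed between the lines and 15 did adjusted over the list alone. By camera 0 of the 5 lists shifted, and 0 had an unadjusted p under 0.05. Of 38 added lists 1 shifted. Of 23 cell division genes 5 were higher in miR164b and 1 lower, with the mitotic kinase genes AUR1 at 446 ± 25.7 against 267 ± 16.8 and AUR2 at 355 ± 30.8 against 221 ± 17.3 (list adjusted p = 0.0012; adjusted p = 0.656 with an estimated correlation). In total 1623 probe sets passed, 708 higher and 915 lower in miR164b. With median centring the split turned to 991 higher and 652 lower, so the balance of directions is not settled. Of 79 genes named by the rule as past the threshold 18 kept their call under every alternative. The LAS call was lost in 11 of 14 alternatives, both scalings and each single array among them, and that of FD in 8. The count was 102 without miR164b replicate 1, 136 without miR164b replicate 2, 228 without miR172a replicate 1, 283 without miR172a replicate 2 and 1018 without either vector array.

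The overlap of the lines was compared among calls against vector. LEA4-5, AT3G02480, LTI30 and HIS1-3 fell in both, as did 34 named genes in all, and EXPA4, PRA1.F1, scpl31 and scpl48 were among 32 named genes that rose in both. Across all probe sets 89 were higher in both lines, 88 lower in both and 28 moved in opposite directions. Independent lists of these sizes would give 6.98, 5.05 and 11.9. Shared vector arrays add to the counts in the same direction, but not to the opposite one. Both contrasts also use the same estimate of spread for each probe set, so their lists are not independent. Across probe sets, which are not independent replicates, the changes in the lines correlated at 0.38 with a covariance of 0.0319. In 100 simulations of unchanged groups with shared vector arrays the values were 0.50 and 0.0146. The simulated correlation was fixed near 0.50 by groups of equal size with a shared control. Changes in 1 line alone lower it, so 0.38 beside 0.50 does not measure what the lines share. With vector array 1 for miR164b and array 2 for miR172a, which leaves no shared control array, the correlation was 0.125 and the covariance 0.0129, and 14 probe sets were called the same way in both lines and 4 in opposite directions. With the vector arrays exchanged the values were 0.187, 0.0181, 18 and 4. Independent lists of the sizes called there would give 0.206 and 0.268 probe sets moving the same way. Both fits took the spread of each probe set from the same miR164b and miR172a arrays, so their lists were not independent even then. The overlap was 2 without either miR164b array, 36 and 22 without miR172a replicates 1 and 2, and 15 and 22 without vector replicates 1 and 2, against 177 probe sets moving the same way with all arrays.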

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

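The tests of the glucosinolate genes in this part were chosen after the results were seen, while the direct contrast of the lines was chosen before.

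A group of 8 named genes passed against vector in both lines in opposite directions. They were picked for that, so the difference between the lines is the sum of both changes and its test adds no independent evidence. Against vector, the miR172a calls of BCAT4, AT2G43550 and AT1G76240 were narrow (adjusted p = 0.0447, 0.0382 and 0.0488). So were the miR164b calls of AT5G33370 and AT2G30930 (adjusted p = 0.0429 and 0.0489). BCAT4 was higher in miR164b than in miR172a by a log2 of 4.35, AT2G25450 by 2.12, AT1G07050 by 2.01, AT2G43550 by 1.98, AT1G76240 by 1.44, AT5G33370 by 1.36 and AT2G30930 by 1.2. AT4G30450 went the other way, with a difference of -2.29, and read 68.0 in miR164b, 122 in vector and 395 in miR172a. Among control probe sets outside the comparisons, the probe set for the 5' end of actin was 1.53 times as bright in miR164b as in vector. In miR172a it was 1.32 times as bright, and in both lines it lay above both vector arrays.

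The rise of 5 genes linked to glucosinolate synthesis in miR164b (BCAT4, GSTU20, AT2G31790, AT2G25450 and UGT74B1) was weighed against scaling and a weak array. With quantile normalization or median centring the smallest of the 5 log2 changes was 1.17, so the changes do not depend on the choice among these scalings. The arrays already had equal trimmed means and similar medians, so this outcome was largely fixed in advance. Array 1 of miR164b had spike-in signals at 57.1% of the vector mean, and without it the smallest change was 1.12. The changes therefore do not come from that array alone, although only 2 of the 5 genes then passed (highest adjusted p = 0.105), with a single miR164b array assumed to vary like the other groups. An effect of miR164b, or of this transgenic line, stays open as a hypothesis. It cannot be told apart from a difference in the growth or handling of these plants, because there was 1 set of miR164b arrays.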

How the results depend on the processing

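Of what follows, only the tests of the added lists and the separate vector arrays were chosen after data had been seen. Counts of probe sets past the threshold are given for miR164b against vector, miR172a against vector and miR164b against miR172a, then for those moving the same way in both lines, beside 407, 1336, 1623 and 177. An offset of 1 gave 103, 406, 683 and 47, and an offset of 64 gave 916, 2241, 2707 and 347. Removal of the 40% dimmest probe sets gave 1136, 2398, 2970 and 409, and the trended and robust prior 1033, 2269, 2781 and 370. Only the 4 arrays compared gave 144, 359, 1018 and 45. An adjusted p under 0.1 gave 964, 2412 and 2948, and a fold of at least 2 without overlap 149, 270 and 299. Leaving out each array gave 9 to 144, 111 to 359, 102 to 1018 and 2 to 36. A vector array of its own for each line gave 14 and 18 probe sets moving the same way, in either assignment, where both fewer arrays and separate controls differ from 177. A lone array was assumed to vary like the other groups, and without an array of the group outside a contrast the counts equal those from 4 arrays, since a lone array adds no residual degree of freedom. With the replicate number as a block the counts were 186, 795, 1104 and 95, but the numbers do not pair the arrays: deviations from group means correlated across probe sets, which are not independent replicates, at -0.011, 0.105 and 0.0787. Quantile normalization gave 400, 1396, 1667 and 174, and median centring 409, 1299, 1643 and 173. The higher share between the lines was 43.6%, and 52.1% and 60.3% with these scalings. Median centring called 1 fixed list in miR172a, the floral list, beside 0 (its adjusted p ranged from 0.05 to 0.316 over the alternatives). SNZ in miR172a, with a log2 change of 0.8513 from 4 arrays (adjusted p = 0.0602), 0.9316 with an offset of 1 (adjusted p = 0.0529) and 0.7505 to 0.952 without single arrays, no longer passed. It passed with the other settings, and its adjusted p ranged from 0.0016 to 0.0944 over all of them. Of 189 results on named genes past the threshold, 183 passed with either scaling, 130 with 4 arrays, 105 with an offset of 1, 189 with an offset of 64, 148 with the block, 187 with the trended prior and 61 to 105 without single arrays, and 0 reversed. The arrays of every call do not overlap, so among these settings only the scalings could have reversed a direction. Fewer residual degrees of freedom accompany the loss of calls with fewer arrays, and for the offsets the cause was not tested. Of the added lists, 4, 8 and 1 were called with the preset correlation and 0 with an estimated one. The latter test also falls to 3 degrees of freedom. With the correlation alone changed 1, 7 and 2 were. Estimates below 0 were taken as 0 there, which is laxer than the preset 0.01. This held for 5 of the 7 and for the 2 lists called between the lines. Of these the cell division list was called with the preset correlation too, and the heat shock and co-chaperone list only then (adjusted p = 0.0481). Signal over background limits dim probe sets, since 3482 lay below 16 on all arrays.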

Other observations

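The tests of this part were chosen after the results were seen, except that of plastid genes against the 25S rRNA control, whose outcome was fixed before its value was computed.

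Other genes also moved in both lines or in 1, with TUB1 and GTR1 chosen after their values were seen. TUB1, a beta-tubulin gene, rose from 271 ± 18.4 in vector to 593 ± 18.5 in miR164b and 629 ± 49.4 in miR172a (adjusted p = 0.0115 and 0.006). GH9C2, an endoglucanase gene named by the rule, rose by a log2 of 0.83 and 0.92. GTR1, a glucosinolate transporter gene, rose in miR172a (log2 0.61, adjusted p = 0.020) but not in miR164b (log2 -0.007, adjusted p = 0.9795). Its difference between the lines passed (log2 -0.62, adjusted p = 0.017). The families BGLU, BZIP, CYP, EXPA, GH, GSTU, IQD, RALFL, SWEET, TET, TRM, UBP, UGT and VPS did not shift as lists against vector or between the lines. Neither did the added lists for meristem, flowering time, auxin, root, secondary wall, touch and defence, response regulators, small RNA or anther genes, nor the 16 mitochondrial genes.

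A hypothesis that named genes of glucosinolate synthesis and transport rise together in miR164b was tested on the 4 further genes with a named probe set, of 32 listed. AOP1, AOP3, GTR1 and GTR2 had a median log2 change of 0.0989, below 0.592, which is the mark set at 0.5 times the smallest rise among the 5 genes noticed. AOP3 lay near the floor at 6.50 in vector. The log2 changes of AOP1, GTR1 and GTR2 (0.16, -0.007 and 0.04) show only that not every named gene rose like the 5. The mark was set from those 5 genes after values were seen, so it cannot decide on a shared rise of synthesis genes. The 4 genes do not test the pathway as a whole, since 28 of the 32 listed genes were not analysed here.

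The genes that differ from vector in both lines may reflect the vector samples. If the RNA state marked by the 25S rRNA control were the cause, miR172a array 2, whose 25S value was near vector, should sit nearer to vector than array 1. Over 144 probe sets called between miR164b and vector from their own 4 arrays, its median shift was 1.16 times that of array 1 (0.555 against 0.480). With 1 array in each state this cannot exclude that state. A difference in the growth or handling of the vector plants, with 2 of 9 cold and dehydration genes lower in both lines, cannot be told apart from an effect shared by both lines, because there was 1 set of vector arrays.

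The lower plastid-encoded transcripts in both lines were weighed in the same way, with single arrays apart: medians relative to the mean over arrays were 0.234 and 0.0736 for the vector arrays, -0.20 and -0.0141 for miR164b, and -0.0396 and -0.00714 for miR172a. Between miR172a arrays 2 and 1 the 69 genes differed by a median log2 of 0.041 (quartiles -0.0879 and 0.166), between 0 and the 0.148 set as the mark for an effect of RNA state, so the test was open. The scaling of the arrays stays open: with quantile normalization and median centring the median nearest 0 was -0.142, within the 0.186 by which arrays of 1 group differed, and the call that held (highest adjusted p = 0.0017) rests on the preset correlation. Plastid genes may simply move together from array to array: their estimated correlation was 0.435, and with that correlation alone changed the lower adjusted p of the lines was 0.533. That account fits these values without excluding others, and no effect of either microRNA on plastid transcripts was shown.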
